A study of Danio rerio with 4 samples.

How the data were processed

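RNA was measured in whole zebrafish embryos of the Tübingen wild-type strain at 48 hours post fertilisation (hpf). Per the labels, embryos had been injected with a splice-blocking antisense morpholino against hace1, whose splice site lies in the part of the transcript that encodes the catalytic HECT domain, or with a standard control morpholino. Per the labels, 6 RNA samples of about 100 embryos each were prepared per group with TRIzol, and 3 of them were pooled into each library, which left 2 libraries per group (A and B). Barcoded libraries were sequenced on an Ion Proton instrument with 2 libraries per chip. Which libraries shared a chip is not given in the sources used here. If both libraries of a group shared a chip, an effect of the chip cannot be told apart from that of the morpholino. Samples were grouped by the injected morpholino in the sample labels. Nothing in the labels says that the pooled libraries came from separate parents or clutches, so p-values measure the spread between pooled libraries, which may be technical.

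Per the submitters' processing notes, the tools included cutadapt 1.2.1, TopHat2 2.0.6, Bowtie2 2.0.2 and DESeq, and the genome build was Zv9. The counting program, its strand setting and the annotation release are not given in the sources used here. The authors deposited estimated counts that need not be whole (94.3% of the values of quantified genes were not whole) on lines for 32512 genes, 232004 exons and 22962 transcripts, the last as each transcript's share of its gene. The authors also deposited a table of log2 values per gene. For 98.9% of the 12216 genes with a count of at least 1 in every library, those deposited log2 values equalled, within 0.001, the log2 of the estimated count divided by a median-of-ratios size factor and centred on the median of the gene over the 4 libraries. All 4 value columns of each kind were matched to a sample by name and 0 were left unmatched. Of the 32512 genes, 19279 (59.3%) were listed at 0 in all 4 libraries, among them genes such as rps6, rpl11 and cdk1 and all 37 genes of the mitochondrial genome. Such a 0 can come from the counting, so of these genes it is said only that they were listed at 0. Current symbols were found for 21939 gene identifiers, 11117 of them among the 13233 genes above 0, and gene names and Zv9 coordinates in the text are those of the deposited table.

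Estimated gene counts summed to between 5192490 and 10413981 per library. Counts were scaled with an own implementation of the trimmed mean of M values (TMM, trimming 30% of log ratios and 5% of mean levels), and values in CPM (counts scaled to a common library size) use these scaled library sizes. Genes were tested when they reached a count of 10 at the median library size in at least 2 libraries and a total count of 15, which left 10832 genes. The comparison of hace1 morphants with control morphants used limma-voom (limma 3.58.1 in R 4.3.3) with the group as the only term and Benjamini-Hochberg adjustment over all tested genes, and a gene was called at an adjusted p below 0.05. The intended quasi-likelihood test of edgeR was not run, nor was DESeq2, since the estimated counts are stored as named pairs inside an annotation file and their unit was recorded as other. Limma-voom, which had been intended as a second test, was used rather than edgeR. For the same reason cameraPR used limma's moderated statistic, and the authors' log2 values, already on a log scale, were tested with no added pseudocount.

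The 28 gene lists, the rule for named genes, the tests and the first set of other settings were fixed before the data were examined. Lists with at least 5 tested members (27 of the 28) were tested with camera from limma on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Camera compares a list with the other genes, while fry asks whether the list moves, on balance, one way. With an estimated correlation, camera takes its degrees of freedom from the few libraries rather than from the genes, so it has little power here. The photoreceptor list, for example, had an estimated correlation of -0.08, below the preset, and still lost its call. A call lost in that form is therefore not evidence of correlated genes. The genes named were hace1 and the 12 largest rises and the 12 largest falls among called genes with a mean of at least 1 CPM, non-overlapping groups and a symbol that is not a placeholder. Also named were, for each list, up to 4 called members with the smallest adjusted p or, where none was called, up to 2 members of highest mean CPM, and any tested member of the NADPH oxidase and Rac, DNA damage and growth arrest, and cardiac contractile lists. The values of 2 genes that this rule would name are not reported here, and these genes stayed in the tests and list counts. A few further genes were chosen after their values were seen, and the text says so where they appear. Exon counts were merged into non-overlapping regions and tested for differential usage with limma's diffSplice, for regions with a count of at least 5 in at least 2 libraries.

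Scripts were tested on simulated data for the comparison of hace1 morphants with control morphants. With 200 changed genes, limma-voom on 10666 simulated genes recovered 27.9% of genes changed 1.5-fold, 72.9% of those changed 2-fold and 96.6% of those changed 4-fold, and 3 of its 130 calls (2.31%) fell on unchanged genes. With no gene changed it called 0 of 10684 genes. The simulation gave both groups the same spread at a given expression level, and no gene a spread of its own. In the data the control pair differed more than the hace1 pair (median absolute log2 difference 0.24 against 0.13), so these rates are only a guide. Camera on 10689 simulated genes found a list raised 1.5-fold and called 0 of the 26 other lists. Genes were simulated independently of each other, so this says nothing about list calls among correlated genes. The lens list, for example, had an estimated correlation of 0.55. The exon test on 8466 genes recovered 100% of 100 genes with an exon changed 4-fold and called 1 gene with no exon change. The changed exons were drawn only from well-covered regions of genes with several such regions. The rate therefore does not hold for genes with few counts per exon, such as hace1.

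Other settings tried were median-of-ratios scaling, scaling without the genes that held over 1% of a library, no filter and a stricter filter (10 CPM in 2 libraries), the letter of the library as a block, each library left out in turn, stricter thresholds and the authors' log2 values. For lists, an estimated correlation, fry and cameraPR were tried. Settings added after the data were seen were limma-trend on log2 CPM, removal of the trend on exonic length in each library (a spline with 5 degrees of freedom), camera with voom weights, the exon usage test and 1 further gene list. Reads of near-identical gene copies and of overlapping genes cannot be separated in these counts, so such genes are given as uncertain. Intervals given for ratios of counts are exact binomial 95% intervals and cover counting error only. Figures and exon tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The site of the morpholino was not located in the genome, since no genome sequence was used here.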

Results

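Whole-embryo RNA sequencing compared zebrafish embryos injected with a morpholino that blocks splicing of hace1 with embryos injected with a control morpholino, both at 48 hpf. Hace1 is a HECT-domain E3 ubiquitin ligase known as a tumour suppressor, and active Rac1 is among its known substrates. The study asked how gene expression changes when hace1 is knocked down. Each group had 2 pooled libraries (A and B). Estimated gene counts summed to 5192490 in control A, 8596019 in control B, 9856173 in hace1 A and 10413981 in hace1 B, and between 13037 and 13079 genes were above 0 in a library. The 10 most abundant genes held 14.0% of the counts in control A, 16.1% in control B, 18.1% in hace1 A and 17.5% in hace1 B. Over 6390 genes with a mean count of at least 100, the median absolute log2 difference was 0.24 between the control libraries and 0.13 between the hace1 morphant libraries, against 0.31 from control A to each hace1 library and 0.25 from control B to each. Control B was thus about as close to the hace1 libraries as to control A.

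The total RNA of hace1 (ENSDARG00000062280, Zv9 chromosome 16, 3677819 to 3713238, 24 exons) was 18.6 CPM in control A, 13.5 in control B, 13.7 in hace1 A and 13.5 in hace1 B. The means were 16.0 ± 3.60 and 13.6 ± 0.134 CPM (SD, n = 2 libraries each), a log2 fold change of -0.19 with a standard error (SE) of 0.22 (limma-voom with Benjamini-Hochberg adjustment, adjusted p = 0.647). A splice-blocking oligonucleotide need not change the total count of its target, so this value does not check the knock-down. The difference was larger without control B (-0.44) and was 0.03 without control A. The use of its exons did not pass the test either (limma diffSplice over 10 exon regions, adjusted p = 0.957), on counts of 107, 116, 128 and 134 per library for the whole gene.

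In hace1 morphants, the ubiquitin ligase gene mdm2 was 2.93-fold higher and the retinal gene rcvrna 3.22-fold lower than in controls. The cell-cycle inhibitor gene cdkn1a was 4.13-fold higher (13.7 ± 2.01 against 55.9 ± 3.08 CPM; SD, n = 2 libraries each, limma-voom adjusted p = 0.000494), and rs1a, which encodes the secreted retinal adhesion protein retinoschisin, was 4.89-fold lower (33.2 ± 2.03 against 6.98 ± 2.23 CPM, limma-voom adjusted p = 0.000585). Of 10832 tested genes, limma-voom with Benjamini-Hochberg adjustment called 299, of which 149 were higher and 150 lower in hace1 morphants, and 126 of these differed by at least 2-fold (62 higher, 64 lower). All 299 had both libraries of one group above both of the other, as had 53.6% of the tested genes. Chance gives 33.3% only where all libraries have the same spread. Here the control pair differed more than the hace1 pair, and all genes come from the same libraries. The share of 53.6% is therefore no measure of a group effect. With genes over 1% of a library left out of the scaling, 137 genes were higher and 245 lower, so the balance between rises and falls depends on the scaling.

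The largest rise was that of loxl3a (ENSDARG00000076306, chromosome 14, 5873063 to 5922749), a gene of the lysyl oxidase family, whose enzymes cross-link collagen. It had 3 counts over the control libraries and 126 over the hace1 libraries, a ratio of 31.5 with a counting interval of 10.5 to 155 (limma-voom adjusted p = 0.000546), and 81.1% of its exon counts in hace1 morphants lay in 2 of its exons. Cldng, a claudin gene, had 7 against 59 counts (ratio 6.32, interval 2.88 to 16.4, limma-voom adjusted p = 0.0495). Cyp11a1, whose product starts steroid synthesis from cholesterol, had 7 against 42 counts (ratio 4.5, interval 2.00 to 11.9, limma-voom adjusted p = 0.0498). The other leading rises included bmb (log2 fold change 2.03 ± 0.20 SE) and the Sm-ring splicing factor gene snrpd1 (1.51 ± 0.22). They also included serping1, which encodes the C1 inhibitor of complement (1.78 ± 0.41), and oc90, which encodes a matrix protein of the ear stones (1.42 ± 0.29). Their limma-voom adjusted p lay between 0.00054 and 0.0454. Besides rs1a, the leading falls were pax6l (-2.02 ± 0.28 SE), the neuregulin receptor gene erbb4a (-1.94 ± 0.44) and abca4b, whose product clears retinoids from photoreceptor discs (-1.92 ± 0.39). These were followed by tmx3 (-1.83 ± 0.38), FEZ2 (-1.74 ± 0.41), the chromatin protein gene hmgb2a (-1.74 ± 0.32), cpne5 (-1.71 ± 0.37) and rcvrna, which encodes the photoreceptor calcium sensor recoverin (-1.69 ± 0.33). The others were the flippase gene atp8a1 (-1.57 ± 0.34), tulp1a, a photoreceptor tubby-like gene (-1.54 ± 0.31), and SHANK2, a scaffold of excitatory synapses (-1.53 ± 0.34). The limma-voom adjusted p lay between 0.00602 and 0.0483.

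**Figure D1:**
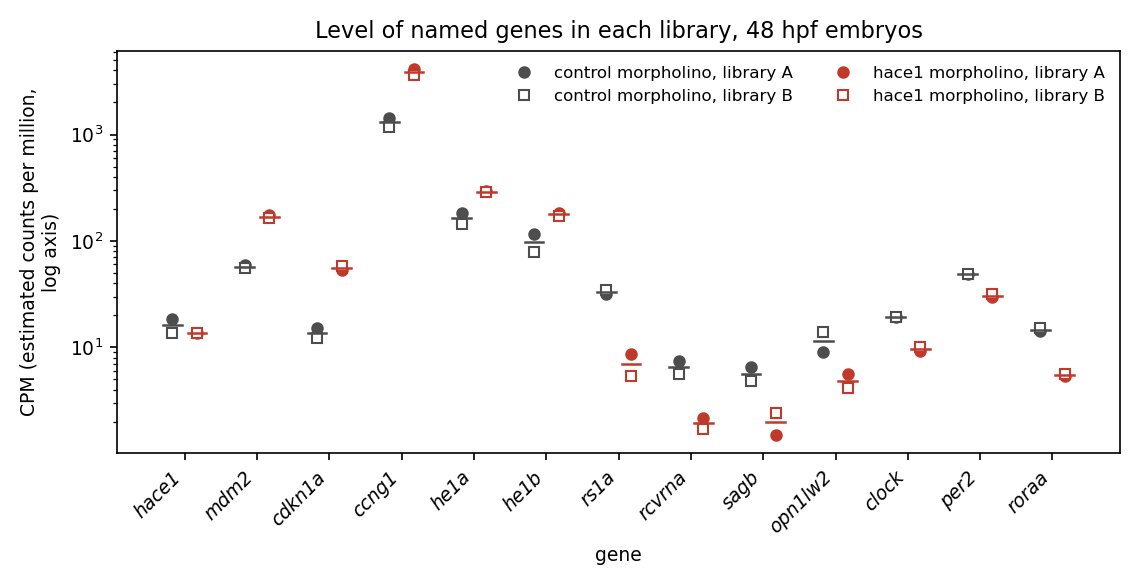
RNA level of named genes in CPM (log axis) in each library, with filled circles for library A, open squares for library B and a bar at the mean of each group of 2 libraries. Mean cdkn1a was 13.7 CPM in controls and 55.9 CPM in hace1 morphants, mean rs1a was 33.2 and 6.98 CPM, and mean hace1 was 16.0 and 13.6 CPM.

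Of the 11 tested members of the DNA damage and growth arrest list, 4 rose, 0 fell and 7 were not called over all genes, and 5 rose and 0 fell when adjusted over the list alone. Among those that rose were cdkn1a (ENSDARG00000076554, chromosome 22, 577559 to 581236), with a log2 fold change of 2.05 ± 0.19 SE, and the cyclin G1 gene ccng1 (ENSDARG00000076667, chromosome 14, 23132061 to 23143178), with 1.58 ± 0.20 (2.99-fold). Another was the ubiquitin ligase gene mdm2 (ENSDARG00000033443, chromosome 4, 22061379 to 22071816), with 1.55 ± 0.16 (2.93-fold). In limma-voom, the adjusted p were 0.000494, 0.00368 and 0.000585. Each was higher in 2 of 2 hace1 libraries than in both controls. Ccng1 rose from 1300 ± 172 to 3888 ± 337 CPM (SD, n = 2 libraries each). The apoptosis gene baxa had a log2 fold change of 0.68 ± 0.17 SE (limma-voom adjusted p = 0.0513, with 0.00204 without control A, 0.00358 without control B, 0.436 without hace1 A and 0.440 without hace1 B), and the other members that were not called lay between -0.20 for ddb2 and 0.30 for plk3 (adjusted p = 0.691 and 0.294, limma-voom). The list as a whole was called higher (median log2 fold change 0.30, camera adjusted p = 0.00085, adjusted p = 0.310 with an estimated correlation). The calls of cdkn1a and mdm2 held with each library left out, while ccng1 lost its call without hace1 A (limma-voom adjusted p = 0.0901) and without hace1 B (0.0549).

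Of 35 annotated retinal photoreceptor genes, 22 were listed at 0, rho among them. Of the 11 tested, 0 rose, 3 fell and 8 were not called over all genes, and 9 fell when adjusted over the list alone. The 3 were rcvrna, the long-wavelength cone opsin gene opn1lw2 (-1.26 ± 0.29 SE) and the arrestin gene sagb (-1.49 ± 0.36). Their limma-voom adjusted p were 0.0356, 0.0464 and 0.0498, and each was lower in 2 of 2 hace1 libraries. The list median was -1.03 on the log2 scale (camera adjusted p = 2.49e-05, adjusted p = 0.310 with an estimated correlation). Of 24 tested neuron genes, 0 rose and 2 fell over all genes, and 5 fell when adjusted over the list alone. The 2 were gad2, an enzyme of GABA synthesis (-0.83 ± 0.16 SE), and the transcription factor gene neurod6b (-0.83 ± 0.18), with limma-voom adjusted p of 0.0295 and 0.0399. The list was called lower (median -0.27, camera adjusted p = 0.0436, adjusted p = 0.464 with an estimated correlation). Its call ended without control B (camera adjusted p = 0.313) and without hace1 A (0.222). Of 23 tested lens genes 0 were called over all genes and 0 when adjusted over the list alone. The list was called lower (median -0.25, camera adjusted p = 0.0317, adjusted p = 0.640 with an estimated correlation). That call ended without hace1 B (0.226) and, with the direction turned, without control B (0.923). The abundant crystallin genes crybb1l2 and crygm2d3 had log2 fold changes of -0.0017 ± 0.27 and -0.43 ± 0.26 SE.

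Of 25 tested members of the circadian clock list, 0 rose and 3 fell over all genes, and 1 rose and 8 fell when adjusted over the list alone. The nuclear receptor gene roraa (-1.42 ± 0.23 SE), the core activator gene clock (-0.99 ± 0.20) and the light-responsive repressor gene per2 (-0.68 ± 0.16) fell. The limma-voom adjusted p were 0.015, 0.0384 and 0.0498. The list median was -0.32 (camera adjusted p = 0.00237, adjusted p = 0.310 with an estimated correlation). Of the 27 lists, fry called this 1 (fry adjusted p = 0.000928). Called genes also differed by exonic length when the tested genes were divided into 5 classes of nearly equal size. The median log2 fold change was 0.07 in the shortest class, with 42 genes called higher and 13 lower. It was -0.12 in the longest class, with 10 genes called higher and 60 lower. Clock and per2 lie in that class (exonic lengths of 6535 and 5418 bases), while roraa (3421) does not. Libraries of 1 group also differed by length. The median difference of hace1 A from hace1 B was 0.08 in the shortest class and -0.08 in the longest. For control A from control B it was -0.06 and -0.04.

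Of 7 tested hatching gland genes, 4 rose and 0 fell over all genes, and 5 rose when adjusted over the list alone. The list was called higher (median 0.83, camera adjusted p = 0.000997, adjusted p = 0.310 with an estimated correlation). The 4 were a pair of genes annotated as the cathepsin ctslb (ENSDARG00000074306 and ENSDARG00000087651 on chromosome 12, 4.37-fold and 4.35-fold) and the hatching enzyme genes he1a (1.78-fold) and he1b (1.87-fold). In limma-voom, the adjusted p were 0.000494, 0.000506, 0.0402 and 0.0413. Each pair consists of near copies that can share reads, so the split between copies is uncertain and the 4 may not be separate rises. The list median and the camera call rest in part on these pairs. The estimated correlation of the list was 0.26, against the preset 0.01. Without hace1 A and without hace1 B the calls of he1a (limma-voom adjusted p = 0.345 and 0.411) and he1b (0.311 and 0.349) ended.

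Muscle and blood gene lists were called higher at the preset correlation. Of 28 tested skeletal muscle genes, 3 rose and 0 fell over all genes, and 9 rose when adjusted over the list alone. Camera called the list higher (median 0.35, camera adjusted p = 2.49e-05, adjusted p = 0.310 with an estimated correlation). The 3 were the myogenic factor gene myf5 (1.24 ± 0.21 SE), mybpc2b, which encodes a fast-muscle myosin-binding protein (0.87 ± 0.18), and the desmin gene desma (0.79 ± 0.17). Their limma-voom adjusted p were 0.0157, 0.0388 and 0.0398. All 17 tested erythroid genes had a positive log2 fold change, 2 rose over all genes and 6 when adjusted over the list alone. That list was called higher (median 0.36, camera adjusted p = 0.000224, adjusted p = 0.310 with an estimated correlation). The 2 were the erythroid transcription factor gene gata1a (1.40 ± 0.26 SE) and the biliverdin reductase gene blvrb (0.88 ± 0.18), with limma-voom adjusted p of 0.0277 and 0.0378. Of 26 annotated cardiac contractile genes, 15 were listed at 0, vmhc among them. Of the 11 tested, 0 were called over all genes and 1 rose when adjusted over the list alone. Camera placed the list higher (median 0.35, camera adjusted p = 0.0307, adjusted p = 0.394 with an estimated correlation). Tpm4a (0.64 ± 0.16 SE, limma-voom adjusted p = 0.0555), vmhcl (0.57 ± 0.19, 0.109) and mybpc3 (0.46 ± 0.17, 0.142) had the smallest p, and the abundant ttna was at 0.21 ± 0.27. The cardiac call ended without control A (camera adjusted p = 0.149) and without hace1 A (0.0701).

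Lists of basic cell functions were called higher at the preset correlation. The oxidative phosphorylation list had 58 of 101 annotated members listed at 0. It had 0 of 41 tested members called over all genes and 0 when adjusted over the list alone, with 39 log2 fold changes above 0. It was called higher (median 0.36, camera adjusted p = 2.49e-05, adjusted p = 0.335 with an estimated correlation), and atp5a1 was at 0.55 ± 0.20 SE. The cytosolic ribosomal protein list likewise had 0 of 58 called either way and 50 above 0. It was called higher (median 0.17, camera adjusted p = 0.000949, adjusted p = 0.310 with an estimated correlation), with rplp0 at 0.47 ± 0.21 SE. Of 40 cell cycle genes, 0 rose and 1 fell over all genes, and 3 rose and 1 fell when adjusted over the list alone. The list was called higher (median 0.26, camera adjusted p = 0.00112, adjusted p = 0.310 with an estimated correlation). The member that fell was hmgb2a, at 98.8 ± 55.8 against 27.6 ± 6.72 CPM (SD, n = 2 libraries each). The log2 fold change of hmgb2a ranged from -1.12 without control A to -2.34 without control B, and its fall was not called without hace1 B. The skin and periderm list had 1 of 24 members called either way, the desmosomal gene pkp3a (1.03 ± 0.17 SE, limma-voom adjusted p = 0.0135). Camera called the list higher (median 0.25, camera adjusted p = 0.000949, adjusted p = 0.310 with an estimated correlation).

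Stress and signalling lists held 1 or 2 called members. Of 25 genes of the unfolded protein, amino-acid stress and heat shock list, 2 rose over all genes and 2 when adjusted over the list alone. These were the collagen chaperone gene serpinh1b (1.40 ± 0.19 SE) and the amino-acid transporter gene slc3a2a (1.05 ± 0.17), with limma-voom adjusted p of 0.00485 and 0.0135. Camera called this list higher (median 0.17, camera adjusted p = 0.0408, adjusted p = 0.310 with an estimated correlation). That list was not called without control B (camera adjusted p = 0.122) or hace1 B (0.0624). Of 13 immediate early genes, 1 rose over all genes and 3 when adjusted over the list alone. The 1 was the cytokine-signalling inhibitor gene socs3b (1.17 ± 0.18 SE, limma-voom adjusted p = 0.0102). The list (median 0.23, camera adjusted p = 0.00633, adjusted p = 0.394 with an estimated correlation) was not called without control A (0.116). Of 11 interferon genes, 1 rose over all genes and 1 when adjusted over the list alone. It was the exonuclease gene isg20 (0.99 ± 0.17 SE, limma-voom adjusted p = 0.0202). The list (median 0.55, camera adjusted p = 0.0115, adjusted p = 0.310 with an estimated correlation) was not called without control B (0.104).

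The antioxidant, vascular endothelium, and glycolysis and hypoxia lists were called higher with 0 members called over all genes or when adjusted over the list alone. The antioxidant list (19 genes, median 0.25, camera adjusted p = 0.0382, adjusted p = 0.339 with an estimated correlation), where gpx4a was at 0.56 ± 0.21 SE, was not called without control A (camera adjusted p = 0.232) or hace1 A (0.108). The vascular list (16 genes, median 0.22, camera adjusted p = 0.0402, adjusted p = 0.310 with an estimated correlation), where efnb2a was at -0.07 ± 0.16 and ephb4a at 0.09 ± 0.16 SE, was not called without control A (0.0577), control B (0.0501) or hace1 A (0.054). The glycolysis list (27 genes, median 0.13, camera adjusted p = 0.0316, adjusted p = 0.310 with an estimated correlation), where gapdh was at 0.45 ± 0.21 SE, was not called without control B (0.104) or hace1 A (0.054).

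**Figure D2:**
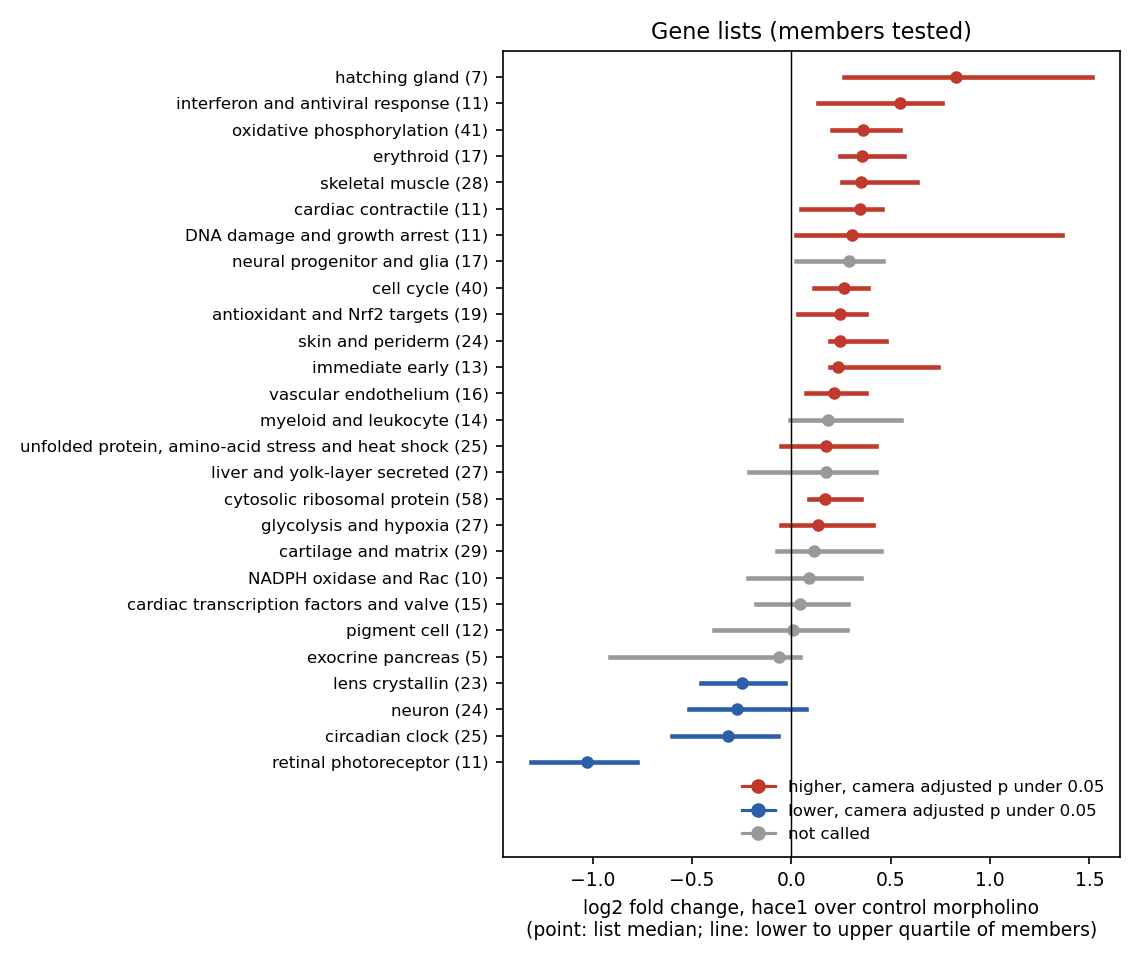
Log2 fold change (hace1 minus control morphants) of the tested members of 27 gene lists, with the median as a point and the quartiles as a line, coloured by the camera call at the preset correlation. Medians run from -1.03 for retinal photoreceptor genes to 0.83 for hatching gland genes, and the 19 called lists comprise 15 higher and 4 lower, against 0 called with an estimated correlation and 1 by fry.

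The genes of the NADPH oxidase and Rac list, which covers Rac GTPases and the oxidase complexes that Rac activates, were not called as a group. Of 18 annotated members, 6 were listed at 0. Of the 10 tested, 0 were called over all genes or when adjusted over the list alone (median 0.09, camera adjusted p = 0.638). Rac1a was at 220 ± 74.7 against 304 ± 17.9 CPM (SD, n = 2 libraries each, log2 fold change 0.52 ± 0.22 SE, limma-voom adjusted p = 0.197) and rac1b at -0.37 ± 0.31 SE (0.502). Single control libraries weigh on both: rac1a was at 0.17 without control A and 0.86 without control B, and rac1b at 0.15 and -1.01. Oxidase subunit genes were at -0.95 ± 0.33 for cybb, 0.81 ± 0.30 for noxo1a, 0.32 ± 0.26 for cyba, 0.36 ± 0.34 for nox1 and -0.10 ± 0.42 for ncf4 (limma-voom adjusted p between 0.125 and 0.917). Rac2 was at 0.24 ± 0.17 and rac3b at -0.26 ± 0.17. Cybb, noxo1a and cyba were at -0.58, 0.66 and -0.09 without control A, and at -1.41, 1.03 and 0.85 without control B. Rac1a, rac1b and these subunit genes passed in limma-voom without control B, where only the hace1 pair gave the spread. Of simulated changes, 27.9% were recovered at 1.5-fold and 72.9% at 2-fold, with the same spread in both groups. These rates may not hold for genes that vary between controls as rac1a does.

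The remaining lists were not called by camera. Of 15 cardiac transcription factor and valve genes, 1 rose over all genes and 1 when adjusted over the list alone, the muscle and heart transcription factor gene mef2ca (0.82 ± 0.16 SE, limma-voom adjusted p = 0.0356), with a list median of 0.04 (camera adjusted p = 0.638). Of 14 myeloid and leukocyte genes, 1 rose over all genes, the cathepsin gene ctssb.1 (1.08 ± 0.23 SE, limma-voom adjusted p = 0.0388), and 2 rose and 1 fell when adjusted over the list alone (median 0.18, camera adjusted p = 0.153). Of 29 cartilage and matrix genes, 1 fell over all genes, the cartilage matrilin gene matn1 (-1.27 ± 0.20 SE, limma-voom adjusted p = 0.0111), and 4 rose and 1 fell when adjusted over the list alone (median 0.11, camera adjusted p = 0.06). This list was called higher without hace1 A (camera adjusted p = 0.0377). Of 17 neural progenitor and glia genes, 0 were called over all genes, and 4 rose and 2 fell when adjusted over the list alone (median 0.29, camera adjusted p = 0.0579). Fabp7a was at -0.77 ± 0.22 SE and mdka at -0.01 ± 0.18. Of 27 liver and yolk-layer genes, 0 were called over all genes and 2 rose when adjusted over the list alone (median 0.17, camera adjusted p = 0.128), with apoa2 at 0.06 ± 0.24 and apobb at 0.51 ± 0.22 SE. Of 12 pigment cell genes 0 were called either way (median 0.01, camera adjusted p = 0.938), with dct at 0.22 ± 0.18 and pmelb at -0.11 ± 0.16 SE. The exocrine pancreas list had 0 of 5 members called either way, with a median of -0.06 and a mean of -0.14 where camera gave an upward direction (camera adjusted p = 0.927). Ctrl was at -0.91 ± 0.49 (-1.76 without hace1 A and -0.02 without hace1 B) and ela2l at 0.04 ± 0.37 SE (0.30 and -0.24). All 13 genes of the mitochondrially encoded list were listed at 0, and that list was not tested.

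How many genes were called depended on which group kept 2 libraries. Limma-voom called more genes without either control library and fewer without either hace1 library. In these fits the lone library of a group is assumed to vary like the pair in the other group. The control pair differed more than the hace1 pair (median absolute log2 difference 0.24 against 0.13). Calls gained or lost in these fits thus also reflect which pair gave the spread. Of the 46 called genes named here, 9 kept their call with each library left out: loxl3a, both ctslb genes, cdkn1a, bmb, mdm2, snrpd1, rs1a and pax6l. The others lost it without at least 1 library, most often a hace1 library, where rcvrna for example had a limma-voom adjusted p of 0.188 without hace1 A and 0.356 without hace1 B.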

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

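The exon usage test, the count of further arms with hace1 removed, the test of a whole-embryo delay, limma-trend with the length trend removed and the division of the length test by list, with its criterion on the shift of each gene, were chosen after the result was seen.

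Exon counts enter none of the gene-level comparisons. Exon usage differed in 3 of 8466 tested genes by limma diffSplice with Benjamini-Hochberg adjustment. In the hatching enzyme gene he1a (diffSplice adjusted p = 0.0106) the last of 5 regions held 65.8% of the counts in controls and 86.4% in hace1 morphants. In the apolipoprotein gene apobb (diffSplice adjusted p = 0.0149) the last of 27 regions held 57.7% and 78.3%. In the fibrinogen gene fga (diffSplice adjusted p = 0.0395) region 5 of 9 held 92.1% and 97.6%. Each share was higher in 2 of 2 hace1 libraries than in both controls. In he1a and apobb the region that gained is the one at the 3′ end. Control A had the lowest share of counts in the last 10% of exonic sequence over all genes (11.0%) and in these regions (63.5% and 54.1%). Control B had an overall share of 12.3%, near hace1 A (12.6%) and hace1 B (12.5%). Its he1a share, 68.1%, still lay below theirs (87.8% and 85.1%), as did its apobb share, 61.3% (83.0% and 73.7%). That rests on a single control library, so exon use is not separated from RNA quality in these 2 genes. In fga, where the region is not the last, control A was also lowest (90.3%, against 94.0% in control B). He1a can also share reads with its near copy he1b.

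Called rises in the DNA damage and growth arrest list, such as cdkn1a, ccng1 and mdm2, are not accounted for by library depth and scaling. Over 3 scalings and without the shallowest library, control A, the smallest log2 fold change of these 3 genes was 1.51 (mdm2, standard error 0.16), while the median gene moved by at most 0.04 between scalings. What stays open is whether these genes respond to the loss of hace1 or to the hace1 oligonucleotide itself, since toxic morpholinos are known to induce them. The series as analysed here has 0 arms in which hace1 was lost by other means or by another oligonucleotide, so these explanations cannot be told apart. The same limit holds for every other difference between the groups given here, those of the photoreceptor, neuron and interferon lists included.

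Camera called the photoreceptor and neuron lists lower at the preset correlation. Neither passed with an estimated correlation (camera adjusted p = 0.310 and 0.464) or by fry (fry adjusted p = 0.0514 and 0.129). The estimated correlation of the photoreceptor list, -0.08, lay below the preset 0.01, so a higher correlation is not why its call was lost. The neuron call also ended without control B and without hace1 A. Lower counts of long genes do not account for the photoreceptor list as the whole cause. With the length trend removed the medians were -0.99 and -0.23, and both lists were still called (camera adjusted p = 1.20e-05 and 0.0389). The neuron genes moved by a median of -0.01 (quartiles -0.03 and 0.04), where 0.18 would bring the list median to the bound of -0.1. By this criterion length is not the whole cause for the neuron list either. An earlier criterion, on the upper quartile of the list, left the neuron list open (0.10 with the trend removed, above the bound). It was replaced after the values were seen. A difference in RNA degradation between the groups cannot be told apart from the group effect: the share of counts in the last 10% of exonic sequence differed by 0.864 percentage points between the group means, against 1.34 between the control libraries and 0.0717 between the hace1 libraries. Most of that gap came from control A (11.0%, against 12.3% in control B, 12.6% in hace1 A and 12.5% in hace1 B), and without it the gap was 0.194 points and both lists were called (camera adjusted p = 2.46e-06 and 0.0249), with 1 control library left. A delay of the whole embryo as the one cause cannot be told apart either, since the lower lens list (median -0.25) and the higher hatching gland (0.83) and cell cycle (0.26) lists go with it, while the skeletal muscle list, with a lower quartile of 0.0603 or above with all libraries and with each left out, was higher, and no stage series was used here.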

How the results depend on the processing

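Limma-trend on log2 CPM, removal of the length trend and camera with voom weights were chosen after the data were seen. The planned edgeR and DESeq2 fits were not run, because the unit of the estimated counts was recorded as other. Against 299 genes, 126 passed with a fold of at least 2 in addition, 30 (19 higher, 11 lower) at an adjusted p under 0.01, and 175 (112 higher, 63 lower, 164 of them shared) with the length trend removed. The first 2 follow from stricter thresholds. The last was a limma-trend fit, and limma-trend on log2 CPM with the length trend kept called 227 genes (122 higher, 105 lower). Part of that drop thus goes with the change of test, and the cause of the rest was not tested. Scaling without the genes over 1% of a library gave 137 higher and 245 lower, and the stricter filter 131 and 197. The other settings gave 213 to 279 genes. Leaving out 1 library gave between 26 genes (without hace1 B) and 2570 (without control B), where the lone library is assumed to vary like the other group. Of 46 named called genes, 34 lost the call without hace1 A, 36 without hace1 B, 1 (cyp11a1, limma-voom adjusted p = 0.106) without control B and 0 without control A. Further calls lost were 12 with the length trend removed, 7 on the authors' log2 values, 6 with limma-trend on log2 CPM, 6 with no filter and 4 with median-of-ratios scaling, and 0 of the 46 changed sign under any setting. Of the named genes not called, 8 passed without control A and 17 without control B. Against 19 called lists, 0 were called with an estimated correlation and 1 by fry, while the totals, which can include lists outside the 19, were 15 to 20 under the other settings and 13 to 17 with 1 library left out.

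With the letter of the library as a replicate block, 914 genes (423 higher, 491 lower) and 17 lists passed, and crybb1l2 had a log2 fold change of 0.0029 against -0.0017 without it. The letters are not said to mark a shared day, and with 2 pairs the deviations of same-lettered libraries had a correlation of -0.009 across 6390 genes.

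The called lens list changed sign, as did genes that were not called. With a library left out, log2 fold changes ranged from -0.44 to 0.027 for hace1, -0.22 to 0.63 for ttna, -0.12 to 0.48 for rplp1, -0.24 to 0.30 for ela2l, -0.43 to 0.41 for crybb1l2, -0.25 to 0.36 for apoa2, -0.0941 to 0.0858 for mdka, -0.0584 to 0.85 for atp5g3b, -0.091 to 0.85 for cyba, -1.01 to 0.15 for rac1b, -0.57 to 0.28 for ncf4, -0.39 to 0.13 for kcnh6, -0.60 to 0.11 for slc8a1a, -0.29 to 0.0805 for ryr2b, -0.12 to 0.42 for gadd45ab and -0.20 to 0.0869 for foxo3b. The camera adjusted p of the lens list, 0.0317 with all libraries, ranged from 1.5e-05 without control A to 0.923, in the opposite direction, without control B. Ela2l was at -0.0022 with scaling that leaves out genes over 1% of a library. Crybb1l2 was at 0.0085 with no filter and 0.0011 on the authors' log2 values, where mdka was at 0.0037. With the length trend removed, efnb2a was at 0.0499, ryr2b at 0.0891, sesn1 at 0.0229 and foxo3b at 0.0875. The causes were not tested. Of simulated 1.5-fold changes 27.9% were recovered at these library numbers and depths, which were not varied, with the same spread in both groups. Genes with few counts in controls have wide intervals.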

Other observations

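The list of ribosome biogenesis factors and the genes outside the named-gene rule were chosen after the result was seen. The test of loxl3a was written before its result was seen, and its count with genes listed at 0 was added after.

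Some genes for the assembly of ribosomes in the nucleolus were among the called rises. Because the list of 150 symbols was written after the called genes were seen and includes genes seen to be called, its counts are not independent evidence of its direction. Of 91 tested members, 86 had a positive log2 fold change, 20 rose and 0 fell over all genes, and 55 rose and 1 fell when adjusted over the list alone. Examples were sdad1 (log2 fold change 1.09 ± 0.18 SE, 2.13-fold), and bop1 (0.86 ± 0.16) and pes (0.71 ± 0.16), the products of which form a complex that matures the large subunit. Others were npm1a, which encodes nucleophosmin (0.74 ± 0.17), and polr1a, which encodes the largest subunit of RNA polymerase I (0.85 ± 0.18). In this order their limma-voom adjusted p were 0.0157, 0.0277, 0.0447, 0.0453 and 0.0399. The 71 members that were not called had a median of 0.44, and 66 of them were positive. The fixed list of cytosolic ribosomal proteins had a median of 0.17.

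Other called genes, picked singly after their values were seen, are no evidence of a shared direction. The bipolar cell transcription factor gene vsx1 fell from 96.3 ± 1.48 to 35.7 ± 2.24 CPM (SD, n = 2 libraries each; log2 fold change -1.43; limma-voom adjusted p = 0.00102). The photoreceptor genes samd7 (-1.27), prom1b (-1.27) and pde6g (-1.07) fell with limma-voom adjusted p of 0.00999, 0.0356 and 0.0431, as did the thyroid hormone receptor gene thrab (-1.47; limma-voom adjusted p = 0.031) and the glucocorticoid-responsive gene fkbp5 (-1.22; limma-voom adjusted p = 0.00523). Next to the ctslb pair on chromosome 12, the unnamed genes si:dkey-269i1.4, si:dkey-26g8.4 and zgc:174153 rose by 2.17, 2.13 and 2.39 on the log2 scale (limma-voom adjusted p = 0.000494 each). Smaller rises there were those of si:dkey-269i1.3 (1.70) and si:dkey-269i1.2 (1.46), with limma-voom adjusted p of 0.000506 and 0.00706. Near copies in that cluster can share reads, so how many separate genes rose is uncertain. The cathepsin L gene ctsla on chromosome 5 rose by 0.89 (limma-voom adjusted p = 0.0388), while ctsl.1 on chromosome 17 was at -0.11 (0.865).

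The reads of loxl3a in hace1 morphants were concentrated in 2 of 14 exon regions. Region 7 from the 5′ end (Zv9 chromosome 14, 5894936 to 5895090) had counts of 0 and 0 in controls and 35.4 and 32.7 in hace1 morphants, and region 8 (5891285 to 5891455) had 0, 1, 11.7 and 21.3. These hold 81.1% of the counts summed over its exon regions in hace1 morphants on 13.7% of the exonic length. Reads of another annotated gene that overlaps it are not a likely source, since 0 other quantified genes are annotated over these exons, and 0 of the other genes of the deposited table when those listed at 0 are included. Reads from a sequence that the annotation lacks, from a repeat or from a shortened loxl3a transcript were not tested, and so whether the whole gene rose stays open.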
